A study of Mus musculus with 21 samples.

How the data were processed

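Total RNA was extracted from the sorted cells with Trizol and a column kit, and biotin-labelled cRNA was made from it and hybridised to Affymetrix mouse expression arrays, per the labels' protocols. The authors deposited 1 table with a value for each of 45101 probe sets on 21 arrays. Its values are intensities on a linear scale that the authors processed with RMA, per the submitters' processing notes, with no version given. RMA usually gives log2 values, and the linear scale was read from the values themselves, whose array medians lie between 25.19 and 31.48. The genome build and scan batches are not given in the sources used here. No scanner files were used here, so the background correction and summary of probes are those of the authors.

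The log2 of each deposited intensity was taken, with no pseudocount and no further normalization. Of the probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. The first kind gave 18194 genes, each by its probe set with the highest mean over all arrays. Entrez identifiers of 34754 probe sets matched a reference gene table of assembly GRCm38.p6, which changed 0 symbols. It was used for names alone, and no coordinates are given.

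Groups came from the sample titles and genotype labels. The main test was limma 3.58.1 in R 4.3.3, with 4 group means over all 21 arrays, moderated variances and Benjamini-Hochberg adjustment over all genes, at a threshold of 0.05. The comparisons were Dot1l-deleted against control in LSK and in GMP, the difference between these effects, and control GMP against control LSK. In all, 36 gene lists and a rule for naming genes were fixed before the data were examined. Sex-linked and sort marker genes were described without a test, and 34 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation was run beside it.

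The rule names Dot1l, the largest changes each way among called genes with no overlap between groups (12 in LSK and GMP), 6 genes for the difference of effects, 8 each way between cell types, up to 4 members of each described list with the smallest p, and Hoxa9, Hoxa10, Meis1, sort marker and sex-linked genes.

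The fit was tested on simulated data with 200 genes changed. For the LSK comparison, over 18194 genes, it recovered 79 of 100 genes changed by 2 on the log2 scale and 17 of 100 changed by 1. For the GMP comparison it recovered 59 of 100 and 11 of 100. In both it called 4 unchanged genes. The simulated noise was normal and independent between genes and arrays, with no array standing apart and no close pair, so these rates need not hold for the real arrays.

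Alternatives fixed beforehand were quantile normalization again, centring on medians, filters on dim genes, other choices of probe set, trended and robust variances, array quality weights, a fold limit of 2, a fit of the compared groups alone, the K number in the titles as a replicate block, Xist as a covariate, each array left out, and other list tests. For the difference of effects and between cell types the K number entered as a level fitted for each number. That fit used only the arrays whose number occurs in both cell types. Alternatives added after the data were seen were the upper quartile of each array as a covariate, the close GMP arrays averaged, the LSK arrays alone without array K1272, array weights estimated gene by gene, and the exact permutation test of list means. Gene-by-gene weights were added because the default estimate of the planned weights stopped before it converged, and both are reported. Fits without the Dot1l-deleted LSK array K1272, with the planned weights and with other filters had been looked at before the added alternatives were chosen.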

Results

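Gene expression was measured on 21 arrays of sorted mouse bone marrow cells. LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction that holds stem and multipotent cells, and granulocyte-macrophage progenitors (GMP) came from mice carrying the inducible Mx-Cre transgene. Control mice had wild-type Dot1l, which encodes a histone methyltransferase, and the other mice carried floxed Dot1l alleles that were deleted after pIpC injection. There were 6 control and 6 Dot1l-deleted LSK arrays, and 5 control and 4 Dot1l-deleted GMP arrays. The labels do not say that each array is a separate animal, so p-values measure the spread between these samples, and the number of arrays limits the precision. The question was what loss of Dot1l does to expression in each cell type. The upper quartile of the log2 values was 6.68 ± 0.07 (SD, n = 6) in control LSK, 6.64 ± 0.22 (n = 6) in Dot1l-deleted LSK, 6.35 ± 0.16 (n = 5) in control GMP and 6.52 ± 0.26 (n = 4) in Dot1l-deleted GMP. The Dot1l-deleted LSK array K1272 stood apart, with an upper quartile of 6.18 and a mean Spearman correlation of 0.684 with its own group.

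Dot1l itself had 2 probe sets, and neither separated the genotypes. The brighter probe set had a log2 level of 6.48 ± 0.30 (SD, n = 6) in control LSK and 6.38 ± 0.35 (n = 6) in Dot1l-deleted LSK, and of 6.74 ± 0.16 (n = 5) in control GMP and 6.22 ± 0.42 (n = 4) in Dot1l-deleted GMP. The dimmer probe set had 6.19 ± 0.48 and 6.003 ± 0.78 in the LSK groups, and 6.13 ± 0.65 and 5.59 ± 1.12 in the GMP groups. Over all probe sets the adjusted p was 0.991 for both in LSK, and 0.348 for the brighter and 0.594 for the dimmer in GMP. Whether these probe sets lie inside the deleted part is not given in the sources used here, so their levels do not check the genotype labels.

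In Dot1l-deleted LSK cells the lowest list means relative to controls belonged to late neutrophil genes, targets of MLL fusion proteins and markers of lymphoid-primed progenitors, but no single gene passed the test over all 18194 genes. Limma called 0 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0769, while 1021 genes had an unadjusted p under 0.05 where chance alone gives 910. The count was 33 without the Dot1l-deleted array K1359, of which 22 were higher, and 0 without array K1272. It was 4 without control LSK K1581 or K1553, 2 without control LSK K1602 or K1604, Dot1l-deleted LSK K1421 or control GMP K1581, and 1 without Dot1l-deleted LSK K1422. Values for single LSK genes are therefore given with their place within the fixed lists.

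Of the 16 measured late neutrophil maturation genes, 15 were lower and 9 were lower when adjusted over the list alone, with a median log2 fold change of -1.78. The mean level of this list differed widely between control arrays, from 3.16 on K1581 and 1.37 on K1601 to -0.43 on K1604 and -0.63 on K1553, which lay among the deleted arrays, and 3 of 6 deleted arrays lay outside the control range. Control K1581 was also the highest LSK array for immediate early genes, at 1.42, and for B cell markers, at 1.03. Lactoferrin (Ltf) had a log2 fold change of -3.36 ± 0.62 (SE), the neutrophil surface protein gene Cd177 -3.33 ± 0.65, the calprotectin subunit gene S100a9 -2.77 ± 0.54 and Ngp -2.49 ± 0.56. Of the 18 MLL fusion targets 17 were lower, 5 of them when adjusted over the list alone. This list shares Hoxa5, Hoxa7, Hoxa9 and Hoxa10 with the Hoxa cluster, Meis1 and Mecom with the stem cell markers and Flt3 with the lymphoid-primed markers. The shifts of these lists are therefore not independent. The homeobox gene Hoxa9 had a level of 10.06 ± 0.43 (SD, n = 6) in controls and 7.17 ± 2.21 (n = 6) after deletion, the cytokine receptor gene Flt3 had 10.19 ± 0.38 and 7.65 ± 1.65, and Eya1 had a log2 fold change of -1.54 ± 0.44. Among 14 lymphoid-primed progenitor markers 12 were lower, 5 when adjusted over the list alone, including Dntt, which encodes terminal deoxynucleotidyl transferase, at -3.99 ± 0.82, Lax1 at -1.68 ± 0.34 and the recombinase gene Rag2 at -1.86 ± 0.56. Among 27 stem cell markers 21 were lower, 2 when adjusted over the list alone, which were Hlf at -3.24 ± 0.76 and Mecom at -2.27 ± 0.66. Of the 8 measured Hoxa genes 5 were lower, 2 when adjusted over the list alone, with Hoxa3 at -2.84 ± 1.04. Dot1l-deleted K1359 lay inside the control range for MLL fusion targets, lymphoid-primed and stem cell markers, with mean levels of 1.16, 1.19 and 0.99, and above it for the Hoxa cluster, at 0.78. Array K1272 was the lowest LSK array for MLL fusion targets, at -1.52, and for lymphoid-primed markers, at -0.73. Hoxa10 had -1.08 ± 0.46 and Meis1, a partner of Hoxa proteins, -1.59 ± 0.67, and both missed the threshold with adjusted p of 0.814 and 0.792.

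Mitosis, oxidative phosphorylation and primary granule genes were higher as lists in Dot1l-deleted LSK cells by camera with a preset correlation. Each of these calls was lost with an estimated correlation, with an adjusted p = 0.292. Among 29 mitosis genes 26 were higher, 2 when adjusted over the list alone, which were the ubiquitin-conjugating enzyme gene Ube2c at 1.43 ± 0.28 (SE) and the checkpoint kinase gene Bub1b at 1.57 ± 0.42. Of 43 oxidative phosphorylation genes 37 were higher, 2 when adjusted over the list alone, Ndufb8 at 1.51 ± 0.35 and Atp5g1 at 1.75 ± 0.47. Atp5g1 had -0.45 when probe sets ending in _s_at, _x_at or _a_at were left out. Over all genes Ndufb8 had a limma adjusted p of 0.209, which reached 0.993 among the alternative settings. Of 13 neutrophil primary granule genes 11 were higher, 4 when adjusted over the list alone and 1 lower by the same measure, with the protease genes Ctsg at 1.59 ± 0.43 and Prtn3 at 1.95 ± 0.54, the transcription factor gene Cebpa at 1.71 ± 0.53 and Mpo at 0.50 ± 0.17. Dot1l-deleted K1359 lay inside the control range for mitosis and oxidative phosphorylation genes, at 0.11 and -1.04, and below it for primary granule genes, at -2.24, and K1272 was the lowest LSK array for mitosis genes, at -1.10. Immediate early genes, DOT1L and elongation complex members, blood transcription factors and interferon response genes were lower as lists by camera with a preset correlation, with 0 members past the threshold when adjusted over the list alone. These calls too were lost with an estimated correlation, with adjusted p of 0.323, 0.292, 0.055 and 0.292, and the latter 3 also without the Dot1l-deleted array K1272.

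Camera with a preset correlation called 12 of 34 lists in LSK, 3 higher and 9 lower. The adjusted p was 1.45e-17 for late neutrophil genes, 4.35e-11 for MLL fusion targets, 1.26e-09 for lymphoid-primed markers, 2.67e-06 for stem cell markers and 0.00262 for the Hoxa cluster. With an estimated correlation these 5 lists had adjusted p of 0.0298, 0.0233, 0.0233, 0.0233 and 0.0361. The calls lost with it had preset adjusted p of 2.7e-08 for oxidative phosphorylation, 7.71e-06 for mitosis, 6.61e-05 for primary granule genes, 0.00135 for immediate early genes, 0.0121 for DOT1L and elongation complex members, 0.0338 for blood transcription factors and 0.0411 for interferon response genes. The 22 other lists had preset adjusted p from 0.05 to 0.995. An exact two-sided permutation test of the mean level of each list over all splits of the 12 LSK arrays, added after the data were seen, passed 0 of 34 lists. Its exact p was 0.0152 for the MLL fusion targets and the Hoxa cluster, 0.0173 for the late neutrophil and lymphoid-primed lists and 0.0238 for stem cell markers, with adjusted p of 0.147, 0.147, 0.147, 0.147 and 0.162. Without the Dot1l-deleted array K1272 the preset adjusted p was 0.7 for DOT1L and elongation complex members, 0.15 for blood transcription factors and 0.477 for interferon response genes, and without control K1581 it was 0.0573 for immediate early genes. The calls of blood transcription factors and interferon response genes also ended without control K1601, K1603 or K1581, the former without Dot1l-deleted K1190 and the latter without Dot1l-deleted K1359. With the upper quartile of each array as a covariate interferon response genes had an adjusted p of 0.0701.

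**Figure D1:**
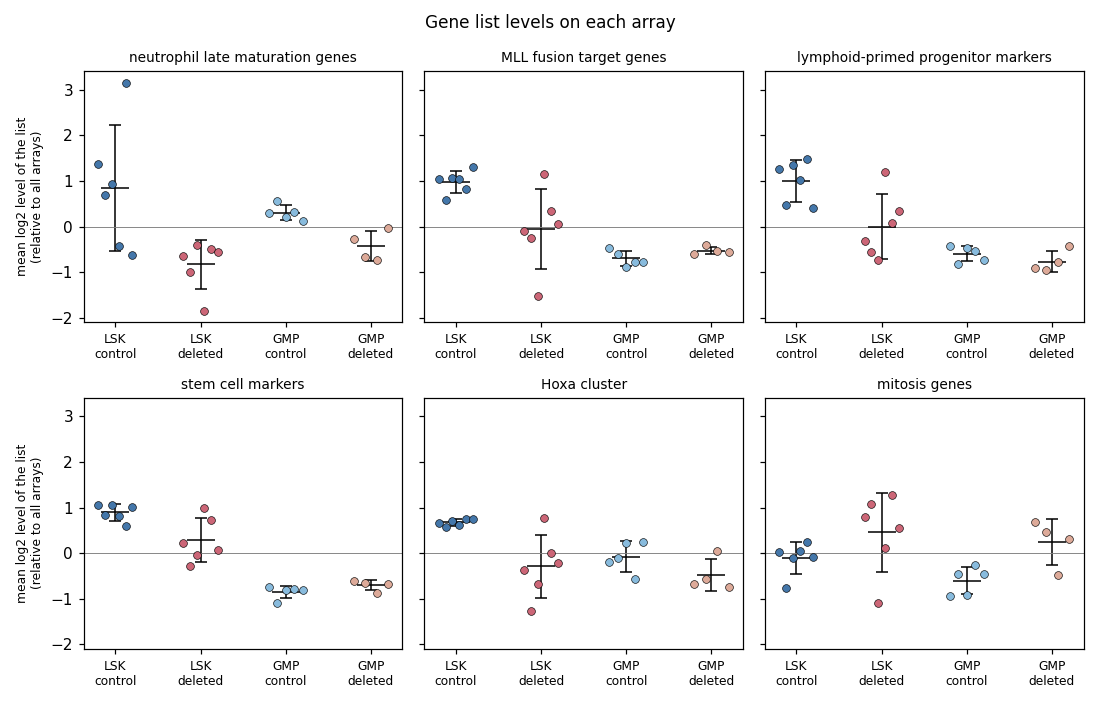
Mean log2 level of 6 gene lists on each array, relative to the mean over all 21 arrays, for the 4 groups on the horizontal axis; points are arrays, and bars are means and SD. The Hoxa cluster was at 0.68 ± 0.07 in control LSK and -0.29 ± 0.68 in Dot1l-deleted LSK, where the arrays spread more widely than the controls.

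In Dot1l-deleted GMP, 15 genes rose and 11 fell at an adjusted p under 0.05. The largest rises with no overlap between groups were Kifap3, which encodes a kinesin-associated protein, with a log2 fold change of 3.99 ± 0.63 (SE), Bsdc1 at 3.18 ± 0.52, Pign, an enzyme gene of membrane anchor synthesis, at 3.003 ± 0.50, Ugp2 at 2.99 ± 0.59 and Spred1, a regulator of Ras signalling, at 2.83 ± 0.50. Ints6l, Dtx3l, Akap11, Zfp386, Smurf2, Nabp1 and Strn rose by 2.34 to 2.70. The largest falls were the eosinophil granule gene Prg2 at -3.20 ± 0.63, Eml2 at -3.10 ± 0.49, Zfand2b at -2.25 ± 0.45, Wrap53, which encodes a telomerase-associated protein, at -2.18 ± 0.30, the isoprenoid synthesis gene Fdps at -2.13 ± 0.42 and Chchd5 at -2.05 ± 0.31. Mogat2, Use1, Vamp5 and the cholesterol transport gene Npc2 fell less, with Npc2 at -1.01 ± 0.20. Of the genes named, Eml2 and Dtx3l were called in all 35 alternative settings. Zfand2b was called in 6 of them, Ints6l in 7, Vamp5 in 9 and Use1 and Npc2 in 10. Ugp2 was called in 11, Fdps in 12 and Prg2 in 14, and the other genes named in more.

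The adjusted p was 0.00432 for Wrap53, Nabp1 and Mogat2, and lay between 0.00734 and 0.0473 for the other genes named. Of all genes, 4.78% had no overlap between the GMP groups, where chance gives 1.59%, and 25 of the 26 called genes were among them. This chance share counts each array as a separate sample, including the close pair K1190 and K1272 described below, and may be too low. The median log2 fold change of all genes was -0.20. With the upper quartile of each array as a covariate this median was -0.07 and 36 genes were called, 11 higher and 25 lower, 19 of them among the 26. A fit of the GMP arrays alone called 18 genes, 7 of them among the 26. The only other probe set of Bsdc1, Ints6l, Chchd5 and Vamp5 went the opposite way, and of 5 other probe sets of Nabp1 2 went the same way. Nabp1 had a log2 fold change of -0.33 when probe sets ending in _s_at, _x_at or _a_at were left out. Dot1l-deleted GMP arrays K1190 and K1272 had a Spearman correlation of 0.982 and a median absolute log2 difference of 0.198, against 0.377 for the next closest pair in the group. All 26 genes kept their direction whichever array was left out, but the lack of overlap fixes this in advance for 25 of them. The count of called genes moved with single arrays. It was 390 without the Dot1l-deleted LSK array K1272, which enters the shared estimate of spread, 125 without the Dot1l-deleted GMP array K1359, 43 without Dot1l-deleted GMP K1421, and 9 when Dot1l-deleted GMP K1190 and K1272 were averaged as 1 sample. It was 9 without Dot1l-deleted GMP K1272, 10 without Dot1l-deleted GMP K1190, 11 without control GMP K1603, 12 without control LSK K1601 or K1603, and 14 without Dot1l-deleted LSK K1421. It was 15 without control LSK K1553, Dot1l-deleted LSK K1091 or control GMP K1581, 16 without Dot1l-deleted LSK K1190 or K1422, and 17 without control GMP K1604.

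**Figure D2:**
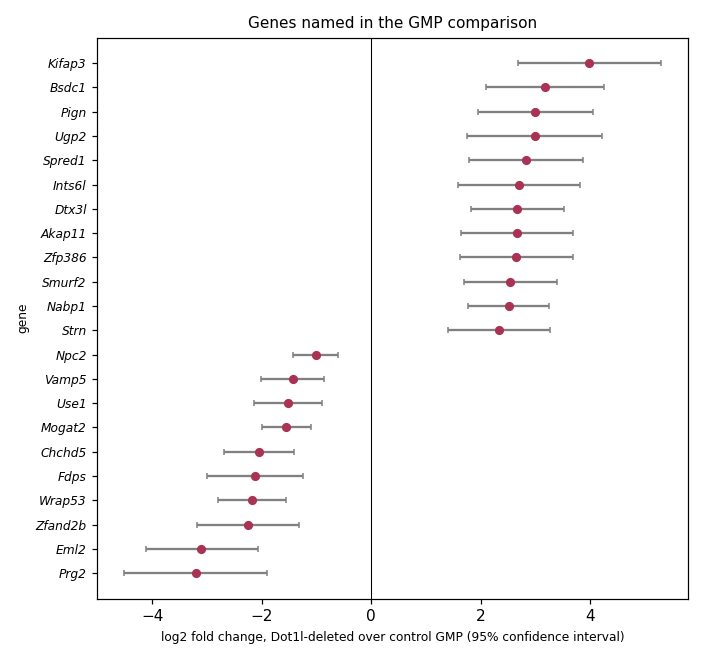
Log2 fold change of Dot1l-deleted over control GMP for the genes named in that comparison; points are limma estimates and bars are 95% confidence intervals. Kifap3 has the highest estimate, 3.99, and Prg2 the lowest, -3.20.

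Among gene lists in GMP, 24 of 29 mitosis genes were higher, 6 when adjusted over the list alone and 1 lower. The kinesin gene Kif11 had a log2 fold change of 2.83 ± 0.81 (SE), Bub1 2.63 ± 0.77 and Hmmr 2.38 ± 0.69, while Cdc20 had -1.09 ± 0.37, which turned positive when probe sets ending in _s_at, _x_at or _a_at were left out. Of 13 heat shock genes 12 were higher, with Hsp90aa1 at 1.26 ± 0.46, while Hspb1 had -0.70. Of 34 MYC and ribosome biogenesis genes 23 were higher, with Ncl at 1.13 ± 0.38 and Polr1b at 1.64 ± 0.52, while Polr1c had -0.95 and Ppan -0.68. In both lists 0 members passed when adjusted over the list alone. For both lists only K1190 and K1272 of the 4 deleted arrays lay above all controls, with mean levels of 0.88 and 0.58 for heat shock and 0.35 and 0.48 for MYC genes. The same arrays had 0.57 and 0.78 for endothelial and stromal markers, where the highest other GMP array had 0.17. For mitosis genes K1359, at -0.47, lay inside the control range. Camera called these 3 of 34 lists with adjusted p of 2.25e-06, 0.00808 and 0.0119, and each had an adjusted p = 0.772 with an estimated correlation. The exact permutation adjusted p was 0.27, 0.351 and 0.392. With the upper quartile of each array as a covariate the preset adjusted p was 0.0318 for mitosis, 0.258 for heat shock and 0.992 for MYC genes, whose median turned negative. The call of the MYC list also ended without control GMP K1601, where the adjusted p was 0.178, or without Dot1l-deleted GMP K1190 or K1272. Without Dot1l-deleted GMP K1421 camera called 6 lists. Hoxa9 had a log2 fold change of -1.27 ± 0.82 and Meis1 -0.07 ± 0.77 in GMP, neither past the threshold. The 31 other lists had preset adjusted p from 0.0551 to 0.992.

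The effect of Dot1l deletion differed between GMP and LSK for 6 genes. Fdps was higher in Dot1l-deleted LSK, at 6.43 ± 0.76 (SD, n = 6) against 4.64 ± 0.30 (n = 6), and lower in Dot1l-deleted GMP, at 5.995 ± 0.79 (n = 4) against 8.12 ± 0.68 (n = 5). Its rise in LSK was not a call by itself, since no LSK gene passed. The control LSK level of Fdps lay under the median gene, 5.54. The difference of effects, GMP minus LSK, was -3.92 ± 0.55 (SE) for Fdps, -3.49 ± 0.56 for Emc8, -2.62 ± 0.39 for Wrap53, 3.39 ± 0.54 for Dtx3l, 3.17 ± 0.53 for Fbxl12 and 3.13 ± 0.54 for Smurf2, with adjusted p from 0.0131 to 0.0331. Camera called 8 of 34 lists for this difference, 7 higher and 1 lower, led by MLL fusion targets with an adjusted p of 1.76e-05, and 0 of them with an estimated correlation, where the lowest adjusted p was 0.266. The number of genes was 15 without the Dot1l-deleted LSK array K1272, 21 without the Dot1l-deleted LSK array K1359, 13 without Dot1l-deleted GMP K1359, 10 without control GMP K1601, 3 without control GMP K1603 and 1 without the Dot1l-deleted GMP array K1190. It was 1 with Dot1l-deleted GMP K1190 and K1272 averaged. With a level fitted for each K number, over only the arrays whose number occurs in both cell types, it was 0. These numbers did not pair the arrays by the check given below.

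Across genes, which are not independent replicates, the LSK and GMP log2 fold changes had a Pearson correlation of -0.244 and a Spearman correlation of -0.274. The Pearson value was 0.102 without the Dot1l-deleted LSK array K1272. At an unadjusted p under 0.05, 23 genes were higher in both and 21 lower in both, where independent lists would give 32.5 and 37.2.

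Control GMP and control LSK cells differed at 2180 genes, 1279 higher and 901 lower in GMP. The 8 largest rises in GMP were Mgam at a log2 fold change of 4.90 ± 0.94 (SE), Ms4a3 at 4.76 ± 0.71, Tmem178 at 4.67 ± 0.43, the protease gene Prtn3 at 4.51 ± 0.57, Cst7 at 4.40 ± 0.55, the metallothionein gene Mt1 at 4.10 ± 0.53, Ndufb2 at 4.08 ± 0.72 and Rgcc at 4.05 ± 0.93. The 8 largest falls were Gcnt2 at -6.33 ± 0.81, the thrombin receptor gene F2r at -6.08 ± 0.78, Dntt at -6.01 ± 0.86, Hlf at -6.01 ± 0.80, Car2 at -5.97 ± 0.76, Ctla2a at -5.55 ± 0.61, Vldlr at -5.34 ± 1.21 and Igk at -5.25 ± 0.73. Of the sort markers, Fcgr3, an Fc receptor gene that marks GMP, was higher by 2.86 ± 0.42, and Kit and Flt3 were lower, at -2.63 ± 0.58 and -5.07 ± 0.60. Cd34, Il7r, Fcgr2b and Slamf1 had adjusted p from 0.0801 to 0.401. Of 13 primary granule genes 11 rose, and of 27 stem cell markers 11 fell over all genes, with camera adjusted p of 2.94e-11 and 2.58e-12 and of 0.0417 and 0.000446 with an estimated correlation. Of 18 MLL fusion targets 9 fell, of 14 lymphoid-primed markers 6 fell, and of 37 interferon response genes 12 fell and 1 rose, with estimated-correlation adjusted p of 0.0373, 0.0373 and 0.0261. Of 43 oxidative phosphorylation genes 20 rose, with a camera adjusted p of 1.36e-06 and an adjusted p = 0.264 with an estimated correlation. Camera called 14 of 34 lists here, 2 higher and 12 lower, and 6 with an estimated correlation. The lower lists included late neutrophil maturation genes, at 0.85 ± 1.38 (SD, n = 6) in control LSK and 0.31 ± 0.16 (n = 5) in control GMP. Their camera adjusted p was 0.0213, with 0.557 at an estimated correlation and 0.227 without control LSK K1581. The upper quartile differed between control GMP and control LSK, and with it as a covariate 593 genes were called, 368 of them among the 2180. The count was 5531 without the Dot1l-deleted LSK array K1272 and between 1111 and 1452 without any 1 of the control arrays LSK K1601, LSK K1603, LSK K1604, GMP K1603 and GMP K1604.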

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

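The tests on array K1359, on transcripts of both sexes and on splits of the LSK arrays for single genes were chosen after the results were seen, as were the upper quartile covariate, the averaged GMP arrays and the count of dim genes in at least 1 group. Of 230 groups examined for a sample far from the rest, 18 had one, where chance gives about 1 in 20.

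In Dot1l-deleted LSK, array K1272 was the lowest for the upper quartile (gap over range 0.866), DOT1L and elongation complex members (0.827), Cd34 (0.834), Gfi1 (0.811), Klf6 (0.633), Lmo2 (0.631) and Mllt3 (0.769). In the same group, array K1359 was highest for Rag2 (0.63) and lowest for Ube2c (0.679), and array K1421 was highest for Slamf1 (0.779). In control LSK, array K1602 was lowest for mitosis genes (0.642), array K1581 highest for Fosb (0.717) and array K1553 lowest for Klf6 (0.654), Lax1 (0.677) and Mpo (0.651). In control GMP, array K1603 was highest for Dtx3l (0.765). In Dot1l-deleted GMP, array K1421 was lowest for Fcgr3 (0.9) and array K1359 lowest for Nabp1 (0.898).

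The Dot1l effect differed between cell types by a test of the difference for Fdps (-3.92), Wrap53 (-2.62), Dtx3l (3.39), Emc8 (-3.49), Fbxl12 (3.17) and Smurf2 (3.13). Camera with a preset correlation called the difference for 8 lists, and all 8 calls were lost with an estimated correlation, where the lowest adjusted p was 0.266. These were MLL fusion targets (median difference 1.51), DOT1L and elongation complex members (0.736), Polycomb group genes (0.394), stem cell markers (0.415), lymphoid-primed markers (0.675), late neutrophil genes (0.799), oxidative phosphorylation (-0.503) and heat shock genes (0.722).

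Other splits of the same arrays bear on how far these counts can be read. At most 100 splits were drawn, of 462 possible for LSK and for the control arrays, 126 for GMP and 378 for the K numbers. For single genes, 3 of 100 splits of the GMP arrays gave at least the 26 genes of the real one, with 72 in the highest other split, and 3 of 100 splits of the K numbers gave at least the 6 genes for the difference of effects, with 45 in the highest other. Both shares lie under 5%, but the GMP splits treat each array as a separate sample. The splits for the difference of effects treat each K number as a separate sample. Dot1l-deleted GMP K1190 and K1272, which the real grouping keeps together, had a Spearman correlation of 0.982. With this pair averaged the counts were 9 and 1, so a chance split is not firmly excluded for either. Some splits called several times the real count, and what those splits share was not examined. For control GMP against control LSK 1 of 100 splits, the real one, gave 2180 genes, with 950 in the highest other, and a chance split is excluded. For LSK the real count was 0, which all 100 splits reach by construction, so they test nothing; the highest other gave 7.

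For gene lists chance was not excluded. In LSK 18 of 100 splits called at least 12 lists, with 16 in the highest other and a median of 9. In GMP 42 of 100 called at least 3, with 10 in the highest other, and for the difference of effects 46 of 100 called at least 8, with 15 in the highest other. Camera at the preset correlation thus called many lists under random groupings of these arrays, and its adjusted p-values cannot be read at face value here. The correlation of -0.244 between LSK and GMP effects was reached or exceeded by 77 of 100 splits, with 0.322 in the highest other.

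The 26 genes called in GMP were weighed against array quality and dim probe sets. With the upper quartile of each array as a covariate, the called genes kept 90.4% of their median absolute log2 fold change, 2.28 against 2.53, and 19 of 26 stayed called. The upper quartile thus accounted for little of the folds of these genes, which were chosen for large changes in the same arrays. The calls themselves moved from 15 higher and 11 lower to 11 higher and 25 lower, so array quality is not excluded. A share of 0% lay under the median gene, 5.54, in both groups, but a large change itself lifts 1 group over it, and 13 of 26 lay under it in at least 1 group, so folds taken against levels near the background stay open. With Dot1l-deleted GMP K1190 and K1272 averaged, 9 of the 26 genes stayed called. All 26 kept their direction, which the lack of overlap between the groups fixes in advance for 25 of them. The Xist level was not balanced between these groups. It was 11.56 to 13.32 on the Dot1l-deleted GMP arrays, 6.24 and 6.16 on control GMP K1603 and K1604, and 12.19 to 13.42 on the other control GMP arrays. With Xist as a covariate 13 genes were called. Dot1l deletion and other differences between the mice stay open.

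The Dot1l-deleted LSK array K1359 lay with the controls for several lists. Partial deletion in the samples of this number was tested by the rank of the GMP array K1359 for MLL fusion targets, which was 3 of 9, but this list was not lower in Dot1l-deleted GMP, at -0.53 ± 0.08 against -0.70 ± 0.16 in controls, so the rank tests nothing. If a control array carried a wrong label, nearly all lists called without it should fall within the control range, and 72.7% of 11 did, with 1 list outside on the side of the other deleted arrays, which does not decide. Partial deletion and a wrong label cannot be told apart here, since no value decides and it is not known whether the Dot1l probe sets lie inside the deleted part.

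Xist and the Y-linked gene Eif2s3y were both high on 4 arrays, LSK control K1601 and K1602 and Dot1l-deleted GMP K1190 and K1272. On these 4, Kdm5d or Uty lay above the 3 arrays with high Xist and low Eif2s3y, but by more than 1 SD of those arrays on 3, since Uty on LSK control K1602 was 2.88 against 2.83 on LSK control K1553. Another 5 arrays with high Xist had Eif2s3y between the limits, which were set after the levels had been seen. Among them, GMP control K1581 had Kdm5d at 7.48 with Xist at 12.22, and Dot1l-deleted GMP K1359 had Uty at 3.21 with Xist at 13.32. RNA of both sexes in 1 sample stays open, and no biological explanation was tested.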

How the results depend on the processing

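Tests added after the data were seen are the upper quartile covariate, the averaged GMP arrays, LSK alone without array K1272, gene-by-gene weights and the exact permutation. The cause of each change was not tested, except that filters test fewer genes and omissions use fewer arrays.

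For LSK genes, 24 of 37 alternatives kept the count of 0. It was 663 with default array weights and 446 with gene-by-gene weights, 3 with the upper quartile, 1 with LSK alone without array K1272 and 2 with all probe sets tested, and leaving out 1 array gave 0 to 33. It was 33 without Dot1l-deleted LSK K1359, 4 without LSK control K1581 or K1553, 2 without LSK control K1602 or K1604, Dot1l-deleted LSK K1421 or GMP control K1581, and 1 without Dot1l-deleted LSK K1422. For GMP genes the count of 26 became 13 with centring, 8 with the mean of probe sets, 14 without probe sets ending in _s_at, _x_at or _a_at, 13 with Xist, 3778 and 7152 with default and gene-by-gene weights and 9 with close arrays averaged. Fitted on the GMP arrays alone the count was 18, with 7 of the 26 among them. With the mean of probe sets 6 of the 26 stayed called. Leaving out 1 array gave 9 to 390. The default weights, which stopped before convergence, gave Dot1l-deleted GMP array K1190 a weight of 0.00801 and the gene-by-gene weights 8.89, so neither count is relied on. For the difference of effects, 6 became 3 with the mean of probe sets, 2416 and 4236 with the weights and 1 with close arrays averaged, and omissions gave 1 to 21. Centring gave 2 higher of 6 against 3 of 6. Between cell types, 2180 became 1417 above the median level, 7054 and 6351 with the weights, 4439 with the compared groups alone and 593 with the upper quartile, and omissions gave 1111 to 5531.

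By the correlation of deviations the K numbers did not pair the arrays, although Xist lay on the same side of 10 in both cell types for 6 of 9: 1 of 9 pairs had a correlation of deviations over 0.1, and 1 of 9 LSK arrays correlated best with its own number. With the number as replicate block the counts were 0 in LSK and 16 in GMP, and Meis1, GMP was 0.0626. For the difference and between cell types a level was instead fitted for each number. That fit used only the arrays whose number occurs in both cell types, and gave 0 and 454.

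For lists, LSK gave 12, 5 with an estimated correlation, 4 with fry and 0 with the exact permutation, and omissions gave 9 to 14. GMP gave 3, 0 with an estimated correlation, fry or exact permutation, 1 above the 25th percentile, 5 with the mean of probe sets or gene-by-gene weights and 6 without those probe sets, and omissions gave 2 to 6. The difference gave 8, 3 above the median level and 0 with an estimated correlation or fry, and omissions gave 6 to 12. Between cell types 14 became 8 above the median level and 6 with an estimated correlation, and omissions gave 13 to 17. The correlation of effects, -0.244, was -0.059 with the upper quartile, -0.078 over different K numbers, 0.077 without replicate K1272 and 0.102 without Dot1l-deleted LSK K1272, and omissions gave -0.323 to 0.102.

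Signs turned without probe sets ending in _s_at, _x_at or _a_at for Bsdc1, GMP (-0.0200), and in GMP for Nabp1 (-0.33), Vamp5 (0.0663), Cdc20 (0.0272), Hoxa10 (-0.17) and Fcgr2b (-0.20), Atp5g1 (-0.45) and Uqcrq (-0.96) in LSK, Hoxa10 (-0.0167), Ndufb8 (0.26) and Atp5g1 (0.27) for the difference and Hoxa10, celltype (0.0890), the comparison of control GMP with control LSK. With the mean of probe sets they turned for Rnf2 (-0.38, difference) and Slamf1, celltype (-0.0233), and with quantile normalization for Dot1l, LSK (0.00447) and its brighter probe set (0.0184 among all probe sets) and Il7r, GMP (0.0903). With the upper quartile they turned for the list MYC and ribosome biogenesis genes, GMP (-0.0708), between cell types for mitosis genes (0.37), cytokine receptors (0.0173) and Dot1l, celltype (-0.0480), and Meis1 in GMP (0.0445). Averaged arrays gave Meis1 0.25 and Il7r 0.0357, default weights Fcgr3 0.20 and Flt3 0.0740, gene-by-gene weights Fcgr3 0.18 and Xist Fcgr3 0.10. Omissions ranged in GMP from -0.85 to 0.32 for Meis1, -0.30 to 0.39 for Fcgr3, -0.44 to 0.16 for Flt3 and -0.20 to 0.0577 for Il7r, and in LSK from -0.62 to 0.21 for Il7r.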

Other observations

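The exact permutation test was chosen after the results were seen. In GMP, 3 lists that camera did not call separated the groups fully, with all 4 Dot1l-deleted arrays outside the range of the 5 controls. The mean level of late neutrophil maturation genes was 0.31 ± 0.16 (SD, n = 5) in controls and -0.42 ± 0.34 (n = 4) after deletion, that of B cell markers 0.28 ± 0.12 and -0.42 ± 0.25, and that of Wnt target genes 0.20 ± 0.19 and -0.11 ± 0.11. The exact permutation p was 0.00794 for each, the smallest that 126 splits can give, and the adjusted p over 34 lists was 0.0899, so none passed. The median of all genes was itself lower in Dot1l-deleted GMP, by a log2 value of -0.20.

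Of 9 K numbers shared by LSK and GMP arrays, 6 had Xist on the same side of a log2 level of 10 in both, a limit set after the levels had been seen. Of the others, K1581 had 5.11 in LSK and 12.22 in GMP, K1190 had 4.33 and 11.92, and K1272 had 9.24 and 11.56.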
